A study of Mus musculus with 25 samples.

How the data were processed

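RNA was measured in 25 libraries of sorted CD4 T cells from C57BL/6NTac mice, in 6 groups given by the labels: wild-type, miR-150 knock-out and miR-150 knock-in, each naive and at day 7 after EAE induction. Per the labels, RNA was extracted with miRNeasy kits, libraries were made with the SMARTer Stranded Total RNA-Seq Pico kit and sequenced in pairs on a NovaSeq 6000. Per the submitters' processing notes, reads were mapped to mm10 and analysed with DESeq2. The aligner, the counting tool, the strand setting and the gene annotation were not given in the sources used here, so values of antisense or overlapping genes are uncertain. The deposited table holds raw counts per Ensembl gene for 25 sample columns, as the authors made them, and all 25 were used. Its values were checked to be whole numbers. Gene symbols, positions and 3' UTRs came from GENCODE M21 on mm10; 45143 of the 46078 gene IDs had a symbol there. No pair of libraries of the same group agreed within sampling noise.

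Genes were kept by edgeR's filterByExpr with the 6 groups (minimum count 10, minimum total count 15), which left 14703. Counts were scaled by TMM and fitted with the edgeR quasi-likelihood model over all 25 libraries, with 1 mean per group and no covariate, and 11 comparisons were tested with Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. All tests were two-sided. Adjusted p-values in the text are from edgeR unless another tool is named. Levels are CPM scaled by TMM, given as mean ± SD over libraries. A fold against a group with no counts used a limit of 3 counts over the group. Counting limits cover counting error only, since reads carry no molecular identifiers here. Gene lists were tested with camera at a preset correlation of 0.01, then with a correlation estimated from the data and with fry, adjusted over the 25 lists of at least 3 tested genes in each comparison. The lists hold T cell states and helper subsets, pathways, reported miR-150 targets and markers of other cell types, written from general knowledge. A list of ribosomal protein genes was added after the results were seen, and its p-values were adjusted over the 11 comparisons. Sites of the miR-150 seed were counted in annotated 3' UTRs of 11131 of the 11217 tested protein-coding genes and compared with 104 control words. The covariance of knock-out and knock-in changes was set against 20 simulated sets without a genotype effect.

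The design, the comparisons, the lists and the rule for naming genes were fixed before the data were examined. The rule names Mir150 and Myb in genotype comparisons. In the 5 main comparisons (day 7 against naive in wild-type, and knock-out and knock-in against wild-type at each stage) it names up to 6 called genes in each direction with the largest fold change. These need a mean of at least 5 CPM and libraries that do not overlap between groups. In other comparisons it names up to 3 in each direction. For each list it names up to 4 called members with the smallest p or, if none is called, up to 2 with the highest mean. Predicted genes, pseudogenes, receptor segments, Y-linked genes and Xist were left out of these parts. The text gives those it needs, and says where a gene outside the rule is named.

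The alternatives were DESeq2's size factors (RLE) in edgeR, DESeq2, limma voom with quality weights, no filter, a stricter filter (5 CPM in at least 4 libraries), only the groups compared in the model, no mitochondrial, ribosomal RNA or haemoglobin genes, library number as a covariate, and leaving out each library in turn. A block on sets of 4 consecutive library numbers, and the median of each called list without each library, were added after the results were seen; the text gives such a median where it shrank by over 1.5 times. The procedure was tested on simulated data with 200 changed genes of 14703. At the wild-type day 7 group sizes it called 50.7% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 77.3% of those changed 4-fold. For knock-out against wild-type at day 7 it called 44.8%, 55.2% and 84.8%. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.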

Results

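The data were gene counts from RNA of sorted CD4 T cells of C57BL/6NTac mice with 3 genotypes at the miR-150 locus: wild-type, miR-150 knock-out and miR-150 knock-in. miR-150 is a microRNA that is abundant in resting lymphocytes. Cells were taken from naive mice or 7 days after induction of experimental autoimmune encephalomyelitis (EAE), an immunization model of multiple sclerosis. There were 5 libraries in the wild-type day 7 group and 4 in each of the other 5 groups, 25 in all. Total counts ran from 6024043 to 49489134 per library, with a median of 16312725. The wild-type naive libraries were on average the shallowest group, at 6024043 to 9351180. Nothing in the labels says whether the libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. Of 46078 genes, 14703 had enough counts to be tested. Between replicates the common biological coefficient of variation was 0.210, and the lowest correlation of log2 counts-per-million (CPM) between any pair of libraries was 0.932. Genes annotated as ribosomal RNA or like it took 20.5% to 32.4% of counts: 22.4% ± 1.32 (SD, n = 4) in naive and 26.4% ± 1.34 (SD, n = 5) in day 7 wild-type libraries. The share was 25.1% ± 1.0005 (SD, n = 4) and 26.4% ± 4.66 (SD, n = 4) in knock-out and 23.1% ± 0.652 (SD, n = 4) and 26.9% ± 1.402 (SD, n = 4) in knock-in libraries at these stages. Replicate 3 of the knock-out day 7 group stood apart: it was the deepest, had the highest such share, and received a weight of 0.144 when libraries were weighted by their fit.

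The Mir150 gene itself was read to check the genotypes. Mir150 (ENSMUSG00000065495, chromosome 7, 45121757 to 45121821 in mm10) gave 0 counts in all 8 knock-out libraries. In wild-type libraries it gave 20.2 ± 4.86 CPM (SD, n = 4) in naive cells and 16.3 ± 5.57 (SD, n = 5) at day 7. With a limit of 3 counts over a knock-out group, its level was at least 758-fold lower than wild-type in naive cells and at least 516-fold lower at day 7, for counting error only. edgeR called the loss at both stages, with adjusted p = 1.24e-09 and 3.53e-09, while limma voom with quality weights gave adjusted p = 0.0938 and 0.0921. Knock-in libraries held 14.3 ± 1.42 CPM (SD, n = 4) in naive cells and 15.9 ± 9.22 (SD, n = 4) at day 7. The knock-in to wild-type log2 fold changes were -0.50 (SE 0.30, adjusted p = 0.9995) and -0.02 (SE 0.27, adjusted p = 0.999). These counts read longer RNA at the gene, and the mature microRNA was not measured. Myb, a transcription factor of lymphoid progenitors and a known miR-150 target, passed the test in no genotype comparison. Its log2 fold changes in knock-out against wild-type cells were 0.30 (SE 0.19, adjusted p = 0.755) in naive cells and 0.40 (SE 0.17, adjusted p = 0.443) at day 7.

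**Figure D1:**
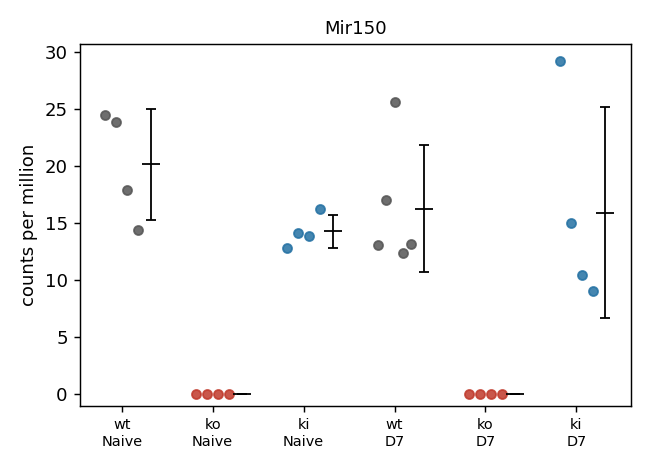
Normalised counts (CPM) of Mir150 in each library, by genotype and stage; points are libraries and black bars give the mean ± SD. Mir150 was at 0 in the 8 knock-out libraries, and its mean was 20.2 in wild-type and 14.3 in knock-in naive cells.

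Day 7 and naive wild-type cells were compared to find what EAE induction changed in CD4 T cells of unmodified mice. Immediate early genes were among those that rose most. Fos, a subunit of the AP-1 transcription factor, went from 2.32 ± 1.15 CPM (SD, n = 4) to 59.9 ± 37.0 (SD, n = 5), a log2 fold change of 4.63 (24.7-fold, SE 0.57, adjusted p = 1.07e-05). Its partners Jun (3.19, SE 0.30, adjusted p = 6.46e-08), Junb (1.99, SE 0.12, adjusted p = 5.09e-12) and Jund (1.07, SE 0.11, adjusted p = 7.19e-07) rose as well. So did Dusp1, a phosphatase that turns off MAP kinases (3.21, SE 0.25, adjusted p = 2.41e-09), and Ppp1r15a, a stress-induced regulator of translation (2.70, SE 0.20, adjusted p = 5.95e-10). Of the 22 tested genes on the list of early response and heat shock genes, 14 rose and 0 fell over all genes tested, and 19 rose and 1 fell adjusted over the list alone. Their median log2 fold change was 1.05, and the list was called with a preset correlation (adjusted p = 2.54e-33) and with an estimated one (adjusted p = 0.000561).

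Other genes that rose by day 7 in wild-type cells included Nr4a2, a nuclear receptor induced by T cell stimulation (2.81, SE 0.53, adjusted p = 0.00264), and Lgals1, a galectin of activated T cells (1.01, SE 0.17, adjusted p = 0.00106). Nr4a2 had few counts, with a mean of 0.371 CPM in naive and 2.64 CPM in day 7 cells. Il1r1, the interleukin-1 receptor used by Th17 cells, rose by 3.34 (SE 0.71, adjusted p = 0.00819), a call that limma voom lost (adjusted p = 0.157). It too had few counts, with a mean of 0.598 CPM in naive and 6.08 CPM in day 7 cells. The amino acid transporter subunits Slc7a5 (0.66, SE 0.13, adjusted p = 0.00336) and Slc3a2 (0.39, SE 0.08, adjusted p = 0.00715) also rose. The Slc3a2 call was lost when sets of consecutive library numbers were a block (adjusted p = 0.0614), a fit chosen after the results were seen. Cebpb, a transcription factor on the myeloid list that T cells also express, rose by 1.30 (SE 0.26, adjusted p = 0.00586). Of 18 naive and quiescent T cell genes, 3 rose over all genes: Btg1, an anti-proliferative factor (0.87, SE 0.07, adjusted p = 3.77e-09), Klf2, which keeps naive T cells in circulation (0.67, SE 0.10, adjusted p = 0.000257), and Igfbp4 (0.49, SE 0.10, adjusted p = 0.00611). The list itself was not called (7 positive, 11 negative, median -0.04; 4 higher and 4 lower adjusted over the list alone; adjusted p = 0.884, and 0.987 with an estimated correlation). Among genes that fell were BE692007 (-0.80, SE 0.08, adjusted p = 1.36e-07), the mitochondrial glycerol-3-phosphate dehydrogenase Gpd2 (-0.78, SE 0.15, adjusted p = 0.00336) and the lysosomal sulfatase Arsb (-0.71, SE 0.14, adjusted p = 0.00345). Wscd2 (-0.72, SE 0.11, adjusted p = 0.00029), the zinc finger gene Zfp3 (-0.93, SE 0.16, adjusted p = 0.00113) and Il6st, the signalling subunit of the interleukin-6 receptor (-0.36, SE 0.06, adjusted p = 0.000301), fell as well. Ms4a4c (-0.98, SE 0.21, adjusted p = 0.00942) was lost without wild-type naive replicate 3 (adjusted p = 0.0692) and with only the groups compared in the model (adjusted p = 0.0543). The call of Rnu1a1, a U1 spliceosomal RNA gene with the largest fold change of the named genes, rested on day 7 replicate 5, which alone held 1077 CPM. Its log2 fold change of 8.50 (SE 1.95, adjusted p = 0.0171) was 1.02 without that library (adjusted p = 0.360). The Rnu1a1 call also ended without naive replicate 1, 2, 3 or 4 (adjusted p = 0.0650, 0.0534, 0.0692 and 0.0660), and with the block on library numbers (adjusted p = 0.276).

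Groups of genes that mark T cell programs and other cells shifted mostly without single members passing. All 13 tested Th17 genes had positive log2 fold changes at day 7 in wild-type cells (median 0.98; 1 rose over all genes, 1 adjusted over the list alone; adjusted p = 1.42e-05 with the preset and 0.431 with an estimated correlation). Of 36 cell cycle genes, 33 were positive (median 0.54; 1 rose over all genes, 1 adjusted over the list alone), with adjusted p = 1.99e-05 and 0.716 with an estimated correlation. Among 30 interferon-stimulated genes 26 were negative (median -0.32, and -0.20 without naive replicate 3; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 3.54e-05 and 0.785 with an estimated correlation. Glycolysis and amino acid uptake genes were called higher (median 0.12; 2 rose over all genes, 5 rose and 1 fell adjusted over the list alone; adjusted p = 0.00144, and 0.188 with an estimated correlation). Oxidative phosphorylation genes had adjusted p = 0.0494, and 0.716 with an estimated correlation (median 0.08, and 0.04 without day 7 replicate 3; 1 rose over all genes, 2 adjusted over the list alone). Markers of CD8 T, NK and gamma-delta T cells, which a CD4 gate should remove, were lower, with median -0.71 (2 fell over all genes, 3 adjusted over the list alone; adjusted p = 0.0273, and 0.461 with an estimated correlation). Among them Trdc, the constant gene of the delta receptor chain, fell by 0.79 (SE 0.15, adjusted p = 0.00298).

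In all, edgeR called 315 genes between day 7 and naive wild-type cells, 173 higher and 142 lower. The count was 144 without wild-type naive replicate 1, 144 without naive replicate 3, 182 without naive replicate 4, 189 without day 7 replicate 3 and 124 higher with 77 lower without day 7 replicate 5. DESeq2 called 499, limma voom 516, edgeR without the low-count filter 894, and edgeR with sets of consecutive library numbers as a block 166.

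**Figure D2:**
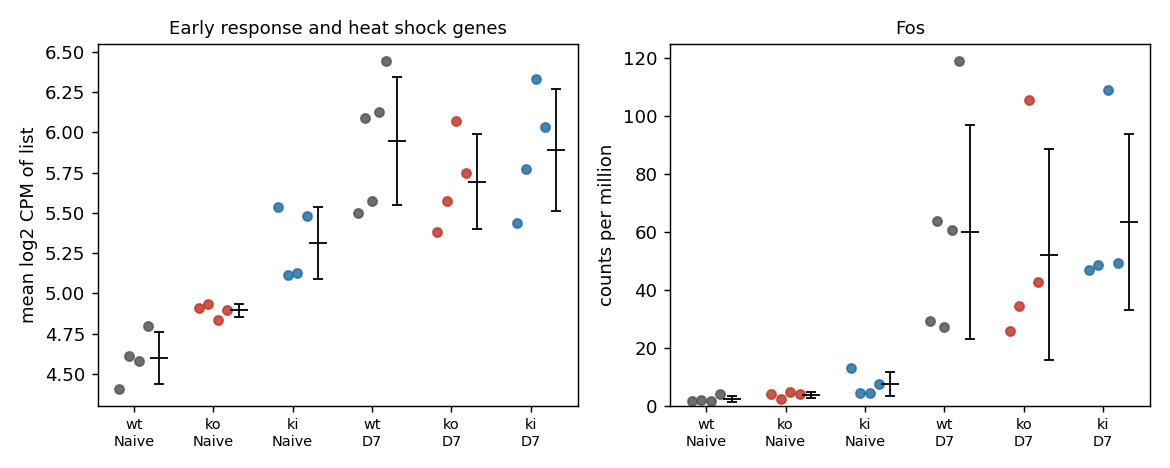
Mean log2 CPM of the early response and heat shock list (left) and CPM of Fos (right) in each library, by genotype and stage; points are libraries and black bars give the mean ± SD. Mean Fos was 2.32 in naive and 59.9 in day 7 wild-type cells.

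The same stages were compared in cells without miR-150. Fos (3.79, SE 0.48, adjusted p = 3.95e-05), Dusp1 (2.14, SE 0.23, adjusted p = 2.76e-06), Jun (2.03, SE 0.28, adjusted p = 0.000117) and Junb (1.21, SE 0.11, adjusted p = 3.51e-07) rose by day 7, with 4 libraries in each group. limma voom lost the Fos call (adjusted p = 0.0717). Btg1 rose by 0.62 (SE 0.07, adjusted p = 1.16e-05) and Wscd2 fell by 0.95 (SE 0.11, adjusted p = 1.65e-05), both in the direction seen in wild-type cells. Tgtp2, an interferon-induced GTPase, fell by 1.03 (SE 0.20, adjusted p = 0.00989), a call lost without day 7 replicate 1 (adjusted p = 0.0524). The early response list was called with either correlation (median 0.50, and 0.32 without day 7 replicate 3; adjusted p = 1.24e-19, and 0.0105 estimated), with 7 genes higher over all genes and 14 higher and 1 lower adjusted over the list alone. All 30 interferon-stimulated genes were negative (median -0.64, and -0.42 without naive replicate 1), 0 of them called over all genes and 25 lower adjusted over the list alone (adjusted p = 4.64e-17, and 0.307 with an estimated correlation). All 36 cell cycle genes were positive (median 0.74, and 0.38 without day 7 replicate 2), with 0 called over all genes and 9 higher adjusted over the list alone (adjusted p = 2.87e-12, and 0.307 with an estimated correlation). B cell markers were lower (16 of 19 negative, median -1.04, and -0.00333 without naive replicate 4; 0 called over all genes and 0 adjusted over the list alone, adjusted p = 0.00165, and 0.511 with an estimated correlation). Markers of CD8 T, NK and gamma-delta T cells were lower as well (13 of 14 negative, median -0.54; 0 called over all genes, 3 lower adjusted over the list alone; adjusted p = 0.0171, and 0.307 with an estimated correlation). edgeR called 60 genes, 31 higher and 29 lower. The count was 30 without naive replicate 1, 29 without naive replicate 3, 34 without day 7 replicate 3 and 92 without naive replicate 4. DESeq2 called 105 higher and 117 lower, limma voom 16, edgeR without the low-count filter 540, and edgeR on the groups compared alone 34.

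In knock-in cells, the same stages were compared. Tox2, a transcription factor of follicular helper cells, rose by 3.72 (SE 0.66, adjusted p = 0.00167) and Il1r1 by 4.48 (SE 0.69, adjusted p = 0.000363), with 4 libraries in each group. Both had few counts in naive knock-in cells, with means of 0.979 and 0.446 CPM. Both genes were highest in day 7 replicate 1, without which Tox2 rose by 2.75 (adjusted p = 0.0190) and Il1r1 by 3.63. Fos (3.07, SE 0.46, adjusted p = 0.000295), Junb (1.34, SE 0.11, adjusted p = 3.48e-08), Dusp1 (1.91, SE 0.22, adjusted p = 8.57e-06) and the kinase Sgk1 (0.62, SE 0.10, adjusted p = 0.000363) rose too. Cxcr5, the chemokine receptor that directs T cells to B cell follicles, rose by 2.34 (SE 0.48, adjusted p = 0.00798), a call lost without day 7 replicate 1 (adjusted p = 0.0845). Ctsw, a protease of cytotoxic lymphocytes (-1.11, SE 0.13, adjusted p = 8.57e-06), and the ubiquitin ligase Nedd4 (-1.06, SE 0.21, adjusted p = 0.00564) fell. Pdcd4, a translation inhibitor on the list of reported miR-150 targets, fell by 0.49 (SE 0.07, adjusted p = 0.000344), as did Pik3r1, the regulatory subunit of PI3 kinase, by 0.29 (SE 0.06, adjusted p = 0.00330). The mean of Pdcd4 was also lower at day 7 in knock-out cells, which lack miR-150 (411 to 350 CPM), and in wild-type cells (429 to 371 CPM). Its fall can therefore not be ascribed to miR-150. All 13 Th17 genes were positive (median 1.46, and 0.93 without day 7 replicate 1), with 2 higher over all genes and 9 adjusted over the list alone (adjusted p = 5.79e-08, and 0.192 with an estimated correlation). The mean log2 CPM of these genes was 2.77 and 2.10 in day 7 replicates 1 and 4, and 0.741 and 0.910 in replicates 2 and 3. The T follicular helper list had 3 genes higher and 1 lower over all genes, and 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.000579, and 0.392 with an estimated correlation). Its mean log2 CPM was 5.34 and 4.86 in replicates 1 and 4, and 4.01 and 4.16 in replicates 2 and 3. Early response genes had a median of 0.32, with 9 higher and 1 lower over all genes and 12 higher and 2 lower adjusted over the list alone (adjusted p = 1.32e-08, and 0.192 with an estimated correlation). Reported miR-150 targets were called lower (12 of 17 negative, median -0.05, mean 0.03; 2 lower over all genes, 3 higher and 6 lower adjusted over the list alone), with adjusted p = 0.0323, and 0.192 with an estimated correlation. CD8 T, NK and gamma-delta T cell markers were lower (10 of 14 negative, median -0.61; 2 lower over all genes, 4 adjusted over the list alone), with adjusted p = 0.0303, and 0.392 with an estimated correlation. edgeR called 297 genes, 149 higher and 148 lower. The count was 156, 163, 141 and 165 without naive replicates 1, 2, 3 and 4, and 107 and 197 without day 7 replicates 1 and 2. DESeq2 called 499, limma voom 720, and edgeR without the low-count filter 890.

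Across the 3 genotypes, 29 genes were called between day 7 and naive cells in every one, 18 higher and 11 lower, out of 521 called in at least 1. Of the 315 genes called in wild-type cells, 282 had the same sign in knock-out cells, where 32 were also called. In knock-in cells 306 had the same sign and 115 were also called. Whether the change by day 7 differed between genotypes was tested as an interaction. edgeR called 0 genes for knock-out (1145 with an unadjusted p under 0.05; DESeq2 1, limma voom 0, edgeR without the low-count filter 30 higher and 173 lower) and 0 for knock-in (558 with an unadjusted p under 0.05; DESeq2 1, limma voom 2, edgeR without the filter 109). As a group, all 22 early response genes had a negative knock-in interaction (median -0.53), with 0 genes called over all genes and 8 lower adjusted over the list alone, and adjusted p = 4.42e-20 with the preset and 0.00940 with an estimated correlation. This interaction includes their higher level in naive knock-in cells. With RLE size factors their median in knock-in against wild-type cells was 0.44 in naive cells and -0.10 at day 7. In the knock-out interaction 19 of these 22 were negative (median -0.52, and -0.34 without wild-type day 7 replicate 5; 0 called over all genes, 5 lower adjusted over the list alone), with adjusted p = 1.82e-07, and 0.423 with an estimated correlation.

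Knock-out and wild-type naive cells were compared for the effect of losing miR-150 before induction. Lgals1, the galectin gene, rose by 0.9997 (SE 0.18, adjusted p = 0.0307), from 9.99 ± 2.09 CPM (SD, n = 4) to 20.1 ± 3.56 (SD, n = 4). The Lgals1 call was lost without wild-type replicate 1, 2 or 3 (adjusted p = 0.209, 0.114 and 0.144) and without knock-out replicate 1, 3 or 4 (adjusted p = 0.101, 0.0663 and 0.210). It was also lost with only the groups compared in the model (adjusted p = 0.0506) with library number as a covariate (adjusted p = 0.0788), and with sets of consecutive library numbers as a block (adjusted p = 0.173). edgeR called 3 genes, 2 higher and 1 lower; DESeq2 called 16 and edgeR without the low-count filter 147. Early response genes were slightly higher (19 of 22 positive, median 0.22; 0 called over all genes, 0 adjusted over the list alone; adjusted p = 0.00166, and 0.544 with an estimated correlation). Mitochondrially encoded genes were lower (9 of 10 negative, median -0.19, and -0.12 without wild-type replicate 4; 0 called over all genes, 2 lower adjusted over the list alone; adjusted p = 0.0121, and 0.544 with an estimated correlation). T follicular helper genes were lower (11 of 14 negative, median -0.11, and -0.06 without knock-out replicate 2; 0 called over all genes, 1 lower adjusted over the list alone; adjusted p = 0.0282, and 0.733 with an estimated correlation).

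The same comparison at day 7 asked for the effect of losing miR-150 after induction. Igsf23, an immunoglobulin superfamily gene on chromosome 7, fell by 1.06 (SE 0.18, adjusted p = 0.0113), from 14.0 ± 1.70 CPM (SD, n = 5) to 6.57 ± 1.44 (SD, n = 4). Pde3b, a phosphodiesterase that degrades cyclic AMP, fell by 0.37 (SE 0.06, adjusted p = 0.0113), from 220.3 ± 8.57 CPM (SD, n = 5) to 170.6 ± 18.3 (SD, n = 4). A further 3 called genes fell outside the rule for naming genes and were chosen after their values were seen: Rtkn2 (4.58, SE 0.90, adjusted p = 0.0487), Ccdc141 (1.24, SE 0.24, adjusted p = 0.0408) and the predicted gene Gm37010 (0.82, SE 0.16, adjusted p = 0.0408). The Igsf23 and Pde3b calls were lost without knock-out day 7 replicate 2 (adjusted p = 0.0687 and 0.0545). With only the groups compared in the model, adjusted p was 0.244 for Igsf23 and 0.434 for Pde3b, and limma voom gave 0.0921 for Igsf23. With sets of consecutive library numbers as a block, adjusted p was 0.0627 for both. edgeR called 7 genes, 4 higher and 3 lower. The count was 15, 2 and 4 without knock-out replicates 1, 2 and 3, and 11, 12 and 4 without wild-type replicates 2, 4 and 5. DESeq2 called 77 genes (31 higher, 46 lower), limma voom 2, edgeR without the low-count filter 349, edgeR on the groups compared alone 1, edgeR without mitochondrial, ribosomal RNA and haemoglobin genes 11, and edgeR with the block on library numbers 2.

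The lists fixed beforehand that were called between knock-out and wild-type cells at day 7 were called with the preset correlation alone. Cell cycle genes had adjusted p = 0.00205, and 0.741 with an estimated correlation (33 of 36 positive, median 0.32; 0 called over all genes, 0 adjusted over the list alone). This rested on knock-out replicate 2, without which the median was -0.06. Th1 and cytotoxic genes were higher (11 of 15 positive, median 0.37; 0 called over all genes, 1 higher adjusted over the list alone), with adjusted p = 0.00765, and 0.624 with an estimated correlation. Interferon-stimulated genes were lower (29 of 30 negative, median -0.22, and -0.11 without wild-type replicate 3; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.00205, and 0.741 with an estimated correlation. Early response genes were lower (17 of 22 negative, median -0.27; 0 called over all genes, 5 lower adjusted over the list alone), with adjusted p = 0.000891, and 0.624 with an estimated correlation. Ribosome biogenesis genes (20 of 25 negative, median -0.09, and -0.04 without knock-out replicate 2; 0 called over all genes, 1 lower adjusted over the list alone) had adjusted p = 0.00584, and 0.624 with an estimated correlation. B cell markers were lower too (15 of 19 negative, median -0.41, and -0.06 without wild-type replicate 3; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.0328, and 0.741 with an estimated correlation.

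Knock-in and wild-type cells were compared for the effect of the knock-in genotype. In naive cells the AP-1 genes Jun and Junb rose. Jun went from 27.9 ± 11.9 CPM (SD, n = 4) to 106 ± 38.0 (SD, n = 4), a log2 fold change of 1.898 (SE 0.29, adjusted p = 0.00913), and Junb from 30.2 ± 1.29 to 48.6 ± 7.76 CPM (SD, n = 4), a change of 0.68 (SE 0.12, adjusted p = 0.0345). The early response list was called with both correlations (21 of 22 positive, median 0.44; adjusted p = 1.63e-28, and 0.00142 estimated), with 2 genes higher over all genes and 11 adjusted over the list alone. Interferon-stimulated genes were lower (28 of 30 negative, median -0.39, and -0.25 without wild-type replicate 3; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 1.37e-11, and 0.498 with an estimated correlation. Myeloid markers were lower (10 of 12 negative, median -0.45, and -0.09 without wild-type replicate 2; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.0280, and 0.498 with an estimated correlation. The Jun call was lost without wild-type replicate 1, 2 or 3 (adjusted p = 0.119, 0.0942 and 0.0736) or knock-in replicate 1 (adjusted p = 0.0976). The Junb call was lost without wild-type replicate 1, 2, 3 or 4 (adjusted p = 0.196, 0.0942, 0.252 and 0.197), without knock-in replicate 1, 2 or 4 (adjusted p = 0.343, 0.0957 and 0.165), by limma voom (adjusted p = 0.0833) and with library number as a covariate (adjusted p = 0.224). With sets of consecutive library numbers as a block, adjusted p was 0.0923 for both. edgeR called these 2 genes only. The count was 0 without wild-type replicate 1, 2 or 3 or knock-in replicate 1, 1 without wild-type replicate 4 or knock-in replicate 2 or 4, and 5 without knock-in replicate 3. At an unadjusted p under 0.05 there were 333 genes; DESeq2 called 5, limma voom 4, edgeR without the low-count filter 59, edgeR on the groups compared alone 10, edgeR with library number as a covariate 1, and edgeR with the block on library numbers 0.

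At day 7 edgeR called 0 genes between knock-in and wild-type cells, with 684 at an unadjusted p under 0.05; DESeq2 and limma voom called 0 and edgeR without the low-count filter 96. Without knock-in day 7 replicate 2 the count was 1. Cholesterol synthesis genes were higher as a group (19 of 22 positive, median 0.22; 0 called over all genes, 1 higher adjusted over the list alone), with adjusted p = 0.000122, and 0.457 with an estimated correlation. Interferon-stimulated genes were lower (28 of 30 negative, median -0.16, and 0.00 without wild-type replicate 3; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.0189, and 0.815 with an estimated correlation.

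Knock-out and knock-in cells were compared directly. In naive cells Tnfrsf25, a death-domain receptor that costimulates T cells, was 0.65 higher on the log2 scale in knock-out cells (SE 0.10, adjusted p = 0.00137, 4 libraries in each group). Igsf23 was lower (-1.26, SE 0.19, adjusted p = 0.00137). Il7r, the interleukin-7 receptor that keeps naive T cells alive, was lower (-0.45, SE 0.09, adjusted p = 0.0201), a call lost without knock-out replicate 1 or 3 (adjusted p = 0.0771 and 0.0949) or knock-in replicate 2 or 3 (adjusted p = 0.0667 and 0.0754). Interferon-stimulated genes were higher in knock-out cells (27 of 30 positive, median 0.59, and 0.28 without knock-out replicate 1; 0 called over all genes, 8 higher adjusted over the list alone), with adjusted p = 5.14e-09, and 0.301 with an estimated correlation. All 8 Th2 genes were positive (median 0.45; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.0153, and 0.249 with an estimated correlation. Migration and adhesion genes were higher (17 of 21 positive, median 0.11, and 0.05 without knock-in replicate 1; 0 called over all genes, 1 higher adjusted over the list alone), with adjusted p = 0.0276, and 0.274 with an estimated correlation. Markers of other cells were higher too: myeloid genes (9 of 12 positive, median 1.01, and 0.67 without knock-out replicate 1; 0 called over all genes, 1 higher adjusted over the list alone) had adjusted p = 0.0153, and 0.274 with an estimated correlation. CD8 T, NK and gamma-delta T cell markers (12 of 14 positive, median 0.51; 0 called over all genes, 0 adjusted over the list alone) had adjusted p = 0.0207, and 0.274 with an estimated correlation. edgeR called 24 genes, 15 higher and 9 lower. The count was 6, 50 and 9 without knock-out replicates 1, 2 and 3, and 10, 7, 15 and 13 without knock-in replicates 1, 2, 3 and 4. DESeq2 called 111, limma voom 137, edgeR without the low-count filter 269 and edgeR with a stricter filter 37.

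At day 7, Igsf23 (-1.22, SE 0.19, adjusted p = 0.00244) and the centrosomal gene Cep170b (-0.996, SE 0.15, adjusted p = 0.00221) were lower in knock-out than in knock-in cells. With only the groups compared in the model, adjusted p was 0.1003 for Igsf23 and 0.0655 for Cep170b. Cbl, a ubiquitin ligase that dampens receptor signalling and a reported miR-150 target, was 0.28 higher (SE 0.05, adjusted p = 0.0162). The Cbl call was lost without knock-in replicate 1 or 2 (adjusted p = 0.0766 and 0.0573), knock-out replicate 3 or 4 (adjusted p = 0.0650 and 0.0588), and with only the groups compared in the model (adjusted p = 0.227). The reported targets were higher as a group (12 of 17 positive, median 0.08, and 0.04 without knock-in replicate 1; 1 higher over all genes, 1 adjusted over the list alone), with adjusted p = 0.0237, and 0.239 with an estimated correlation. Npm1, a nucleolar chaperone of the ribosome biogenesis list, was lower (-0.35, SE 0.07, adjusted p = 0.0184). The Npm1 call was lost without knock-in replicate 1 or 2 (adjusted p = 0.0800 and 0.0522), knock-out replicate 3 or 4 (adjusted p = 0.0967 and 0.0703), and with only the groups compared (adjusted p = 0.175). Ribosome biogenesis genes were lower as a group (21 of 25 negative, median -0.11; 1 lower over all genes, 2 adjusted over the list alone), with adjusted p = 0.000387, and 0.299 with an estimated correlation. B cell markers were lower (17 of 19 negative, median -1.005, and -0.18 without knock-in replicate 4; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.00176, and 0.781 with an estimated correlation. Their mean log2 CPM was 2.25 in knock-in replicate 4 and -0.207 to 0.983 in the other 3 knock-in libraries. In that library Igkc, singled out after its values were seen, was at 198 CPM, against 5.85 to 12.9 in the other 3. CD8 T, NK and gamma-delta T cell markers were higher (10 of 14 positive, median 0.38, and 0.18 without knock-out replicate 2; 0 called over all genes, 4 higher adjusted over the list alone), with adjusted p = 0.0258, and 0.330 with an estimated correlation. edgeR called 55 genes, 20 higher and 35 lower. The count was 20, 15 and 21 without knock-in replicates 1, 2 and 4, and 35, 23 and 28 without knock-out replicates 2, 3 and 4. DESeq2 called 137, edgeR without the low-count filter 404 and edgeR on the groups compared alone 1.

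A microRNA lowers transcripts that carry its seed match. Genes with an 8mer or 7mer-m8 site of miR-150 in their 3' UTR were therefore compared with the 9303 genes with neither. Some of these 9303 held a shorter 6mer match, since 4785 genes had a 6mer or larger site. Genes with an 8mer site numbered 538 and genes with a 7mer-m8 site 1828. In knock-out against wild-type cells the genes with an 8mer site were shifted by 0.00 on the log2 scale in naive cells (adjusted p = 0.689) and 0.03 at day 7 (adjusted p = 0.327). In knock-in against wild-type cells the shifts were -0.01 (adjusted p = 0.845) and -0.02 (adjusted p = 0.413). In knock-out against knock-in cells at day 7 the shift was 0.05 (adjusted p = 0.109, and 0.0693 with an estimated correlation), and 2 of 104 control words gave a shift at or above it. No 8mer shift passed the test. The 7mer-m8 shift in the same comparison was 0.03 (adjusted p = 0.368), and passed only with an estimated correlation (adjusted p = 0.0302); 20 of 104 control words gave a shift at or above it, so it cannot be ascribed to the miR-150 seed.

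Whether the knock-out and knock-in alleles moved genes in opposite directions was tested over 14702 genes. Both changes were taken against the same wild-type libraries, which alone makes them covary. The covariance of the log2 fold changes was 0.0827 in naive cells and 0.0663 at day 7, against 0.0896 and 0.0776 in simulated sets without a genotype effect (SD 0.00289 and 0.00383 over 20 sets). Simulated genes varied independently, whereas real ones can move together (estimated correlation 0.435 among ribosomal protein genes). The simulated SD is therefore too narrow to judge the gap, which decides nothing about direction. With the wild-type libraries divided between the comparisons, the covariance was 0.0119 in naive cells (-0.00635 to 0.0212 over 12 divisions) and -0.0136 at day 7 (-0.0342 to 0.000972 over 20). No gene was called in both comparisons at either stage. By edgeR the calls numbered 3 and 2 in naive cells and 7 and 0 at day 7, so few that an overlap of 0 says nothing about direction.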

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

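The tests of handling, of transcript length and of chromosome 7, and the list of ribosomal protein genes, were chosen after the results were seen; the length test was also revised after its result was seen.

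Single libraries lay far from the rest of their group in 7 of 82 group values, and chance gives about 1 in 20. The rRNA-like share was 20.5% in wild-type naive replicate 1, 23.6% in knock-out naive replicate 2 and 24.1% in knock-in naive replicate 2. Pde3b was at 221.6 CPM in knock-out naive replicate 2. Fos was at 109 CPM in knock-in day 7 replicate 3, Junb at 155 CPM in wild-type day 7 replicate 5, and Rnu1a1 at 1077 CPM in that same library. Between genotypes, the change of the early response list by day 7 was smaller in knock-in than in wild-type cells (adjusted p of the interaction 0.00940 with an estimated correlation). This includes the higher level of the list in naive knock-in cells. With RLE size factors its median in knock-in against wild-type cells was 0.44 in naive cells and -0.10 at day 7 (8 of 22 positive).

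The early response and heat shock genes were higher at day 7 and in naive knock-in cells. The wild-type median was 1.06 after all libraries were thinned to 6024043 counts and 1.05 before. Thinning keeps each gene's expected share of the counts, so it could hardly move this median and decides little about depth. Receptor signalling after induction as the whole cause is argued against: 11 receptor-induced genes outside the list had a median of 0.19 (quartiles -0.01 to 0.35). Among them, however, Nr4a2 rose by 2.81, from a naive mean of 0.371 CPM. Differences in how cells were handled stay open and may contribute, since the list also differed between naive groups, where no induction took place (adjusted p = 0.00142 with an estimated correlation); the knock-in allele is a biological explanation of that difference that was not tested apart. The list's shift was the largest of its splits at day 7 in wild-type cells (1.04, highest of the other splits 0.839, 1 of 60 as large). It was also the largest in naive knock-in cells, by a small margin (0.361, highest other 0.322, 1 of 35). There 1 of 35 is the smallest share the splits can give. The split tests were not adjusted for their number, so chance is not excluded for either shift.

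Igsf23 and Pde3b, both lower in knock-out cells at day 7, lie on chromosome 7 with Mir150. Of 883 chromosome 7 genes more than 10 Mb from Mir150, 8 (0.906%) had p under 0.05 in knock-out against wild-type cells at both stages with one sign, against 93 of 13689 (0.679%) on the other chromosomes (two-sided Fisher's exact p = 0.400). An effect linked to the locus along the chromosome and an effect of lost miR-150 cannot be told apart for these genes, since so few moved.

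Ribosomal protein genes, 80 in all, were lower in knock-out than in knock-in cells at day 7 (median -0.27, 78 negative; adjusted p = 0.0229 with an estimated correlation). Knock-out replicate 3 alone is argued against by a median of -0.26 without it, while the rRNA-like share stays open, since leaving out those genes hardly moved the median (-0.28) and so decides nothing. Genes matched on length and level had a median of -0.0128 (lower quartile -0.117), and -0.07 when each matched gene is counted once. The length matched was that of the longest annotated transcript of each gene, coding or not. It need not be the transcript that was sequenced, so transcript length stays open. Other splits of these libraries decide nothing about chance, since the list was chosen on them (0.270; highest of the other splits 0.230; 1 of 35 as large). An effect of miR-150 stays open: between knock-out and wild-type cells the median was -0.24 at day 7 (0 of the negative genes called; adjusted p = 0.0229 with an estimated correlation), and -0.11 in naive cells (0.202); reads shared with ribosomal protein pseudogenes were not tested.

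For counts of called genes, other splits of the same libraries were fitted alone. For day 7 against naive the real count was far above every other split tried, which argues against chance. This held in wild-type cells (320, highest other 6, 1 of 60 splits), in knock-out cells (34, highest other 6, 1 of 35) and in knock-in cells (374, highest other 1, 1 of 35). For knock-out against knock-in in naive cells the margin was smaller (27, highest other 18, 1 of 35). The smallest share possible there is 1 of 35, and the split tests were not adjusted for their number, so chance is not excluded. Chance cannot be excluded for knock-out against wild-type in naive cells (2; highest other 40; 4 of 35) and at day 7 (1; highest other 3; 6 of 60), nor for knock-in against wild-type in naive cells (10; highest other 28; 5 of 35). The same holds for knock-out against knock-in at day 7 (1; highest other 69; 4 of 35). Where the real count was 0 every split reached it, so the splits decide nothing: knock-in against wild-type at day 7 (highest other 70; 60 of 60) and both interactions (highest other 1 and 3; 60 of 60 in each). Some of these splits called 40, 70 and 69 genes, many more than the real ones. What set those splits apart was not tested. The 8mer shift between knock-out and knock-in cells at day 7 was the largest of its splits by a small margin (0.0506; highest other 0.0494; 1 of 35). It did not pass its camera test (adjusted p = 0.109, and 0.0693 with an estimated correlation), though only 2 of 104 control words reached it. An effect of the seed is therefore neither shown nor excluded.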

How the results depend on the processing

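The control words of 8 bases, the protein-coding background for seed sites the ribosomal protein list, the block on library numbers and the list medians without 1 library were chosen after seeing the data; all other alternatives were chosen before. RLE scaling kept every count of called genes within 1.5 times the reported one. DESeq2 called 499 genes for day 7 in wild-type, 2.2e+02 in knock-out (105 higher, 117 lower) and 499 in knock-in cells, 16 and 77 for knock-out and 5 for knock-in (naive) against wild-type, 1 in each interaction, and 111 and 137 for knock-out against knock-in. limma voom called 516, 16 and 720 by day 7, 2 for knock-out at day 7, 4 for naive knock-in, 2 in the knock-in interaction and 137 for naive knock-out against knock-in. No filter, in the same order of comparisons, gave 894, 540 and 890 by day 7, 147 and 349 for knock-out, 59 and 96 for knock-in, 2.0e+02 (30 higher, 173 lower) and 109 for the interactions, and 269 and 404 for knock-out against knock-in; the stricter filter gave 37 for the last in naive cells. Only the groups compared gave 34 for day 7 in knock-out cells, 1 for knock-out at day 7, 10 for naive knock-in and 1 for knock-out against knock-in at day 7. Without mitochondrial, ribosomal RNA and haemoglobin genes knock-out at day 7 gave 11, and library number as a covariate gave 1 for naive knock-in. Sets of 4 consecutive library numbers as a block, read from the order of the numbers alone and not named in the labels, gave 166 for day 7 in wild-type cells, 2 for knock-out at day 7 and 0 for naive knock-in; wild-type day 7 replicate 5 was alone in its set. The other counts stayed within 1.5 times. Of 275 list tests 63 were called, 4 with an estimated correlation and 8 by fry. The 7mer-m8 shift of 0.0257 was called only with an estimated correlation (adjusted p = 0.0302), and 20 of 104 control words reached it. The covariance with divided wild-type libraries was 0.0119 in naive cells (-0.00635 to 0.0212 over 12 divisions) and reversed to -0.0136 at day 7 (-0.0342 to 0.000972 over 20). The cause was not tested. Leaving out 1 library gave 144 to 464 genes for day 7 in wild-type, 29 to 92 in knock-out and 107 to 376 in knock-in cells, 2 to 3 and 2 to 15 for knock-out, 0 to 5 and 0 to 1 for knock-in, 0 to 0 for each interaction, and 6 to 50 and 15 to 57 for knock-out against knock-in. Of called values of named genes, the call was lost in 236 refits without 1 library and kept in 639, 29 with only the groups compared, 26 with the block on library numbers, 17 by limma voom, 5 with library number, 3 without a filter and 1 each by DESeq2, RLE and the removal of mitochondrial and ribosomal RNA genes. Genes with few counts were read with the least depth in the wild-type naive libraries. The labels give no shared replicate numbers, so no fit was paired on them and the block on library numbers was the only one, and sex was not a covariate because all libraries show one sex pattern.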

Other observations

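The test of ribosomal protein genes was chosen after the called genes were seen. The lists in this paragraph were called with the preset correlation alone. By day 7 in knock-out cells, T follicular helper genes were higher (12 of 14 positive, median 0.37; 1 higher over all genes, 7 adjusted over the list alone), with adjusted p = 1.97e-06, and 0.307 with an estimated correlation. All 13 Th17 genes were positive there (median 0.57, and 0.28 without day 7 replicate 2; 0 called over all genes, 2 higher adjusted over the list alone), with adjusted p = 0.00186, and 0.353 with an estimated correlation. Cholesterol synthesis genes were higher as well (21 of 22 positive, median 0.15, and 0.0991 without naive replicate 2; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.00186, and 0.353 with an estimated correlation. In knock-in cells, 35 of 36 cell cycle genes were positive (median 0.91, and 0.54 without day 7 replicate 1; 2 higher over all genes, 8 adjusted over the list alone), with adjusted p = 3.36e-09, and 0.392 with an estimated correlation. Their mean log2 CPM was 4.05 and 3.56 in day 7 replicates 1 and 4, but 2.62 and 2.66 in replicates 2 and 3, within the naive range of 1.95 to 3.05. Between knock-out and knock-in naive cells, Th1 and cytotoxic genes were higher in the knock-out (13 of 15 positive, median 0.68; 0 called over all genes, 2 higher and 1 lower adjusted over the list alone), with adjusted p = 0.00101, and 0.249 with an estimated correlation.

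Lists not yet described in a comparison were these. Regulatory T cell, dendritic cell, stromal and endothelial, erythroid and platelet, T cell identity, naive and quiescent T cell, and PI3K, Akt and Foxo genes were called as a group in none of the 11 comparisons. Erythroid and platelet genes by day 7 in knock-out cells, and PI3K, Akt and Foxo genes in knock-out against wild-type naive cells, came nearest to it (adjusted p = 0.0597 in both). T cell activation and memory genes were called by day 7 in knock-out cells (19 of 24 positive, median 0.14, and 0.08 without day 7 replicate 2; 1 rose over all genes, 1 adjusted over the list alone), with adjusted p = 0.0171, and 0.522 with an estimated correlation. There the transcriptional regulator Id2 rose by 0.78 (SE 0.15, adjusted p = 0.00886), a call lost by limma voom (adjusted p = 0.0792) and with only the groups compared (adjusted p = 0.131). Mitochondrially encoded genes were higher by day 7 in knock-out cells (9 of 10 positive, median 0.17, and 0.11 without day 7 replicate 2; 0 called over all genes, 0 adjusted over the list alone), with adjusted p = 0.00327, and 0.307 with an estimated correlation.

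Ribosomal protein genes also rose together by day 7 in wild-type cells (79 of 80 positive, median 0.26, 19 called higher), with adjusted p = 0.0329 with an estimated correlation. In knock-out cells the median was 0.13 with 0 called (adjusted p = 0.202 with an estimated correlation). In knock-in cells the median was 0.21 with 6 called higher (adjusted p = 0.0646 with an estimated correlation).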
